A study of Mus musculus with 18 samples.

How the data were processed

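Gene expression was measured in forelimb digit tips of C57BL/6 mouse embryos with 2-colour Agilent arrays of 60-base probes, 18 arrays in 6 groups of 3. Per the labels, RNA was extracted with Trizol and amplified and labelled with a low-input Agilent kit, with Cy3 for the digit-tip RNA and Cy5 for a reference pool of RNA from 11 cell lines mixed with RNA of 129ES embryonic stem cells. The labels give the sex as mixed. The arrays were on 5 slides and were scanned on 2 dates, with replicates 1 and 2 of every group in the first scan batch and replicate 3 in the second. Dyes were not swapped, so a dye effect of a probe cancels only in differences between groups.

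The deposited scanner files hold, per the file headers, output of Agilent Feature Extraction 9.5.1.1, with the mean spot intensity and the local background intensity of each channel. They also hold intensities that the software had background-subtracted and dye-normalized and, per the file headers, a log10 ratio of Cy5 over Cy3. The value table of the series matrix, for 25030 of the probes, is deposited with its scale and centring unstated. Set against each array's scanner values, with probes centred over arrays, it followed log10 of sample over reference at r = 0.991 to 1.000, so the log10 scale and the direction were taken from that comparison. A constant per probe had been added, whose origin stays unknown. Its column medians for replicates 1, 2 and 3 were 2.45, 2.45 and 2.45 for WT E14.5, 2.48, 2.48 and 2.47 for WT E16.5, 2.47, 2.47 and 2.47 for WT E18.5, 2.44, 2.44 and 2.46 for KO E14.5, 2.47, 2.46 and 2.47 for KO E16.5, and 2.47, 2.46 and 2.48 for KO E18.5. This table served as an alternative only.

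The deposited spot intensities were corrected in R 4.3.3 with limma 3.58.1, using normexp with an offset of 50, and normalized by loess within each array. Control spots (1417 of 43451) were then left out, as were the 4 to 34 outlier spots per array, and spots of a probe were averaged. All 42006 probe names are IDs that no column or table used here pairs with a gene, so each probe was tested by itself, and the Fzd6 probe, the gene lists and the choice among probes of a gene were not analysed here. A probe was tested if it was well above background in Cy3 on all 3 arrays of at least 1 group and had at least 2 values in each group, which left 27989 probes. On single arrays 25100 to 29081 probes were well above background in Cy3, and no Cy3 spot was saturated.

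One mean per group was fitted to all 18 arrays with limma's lmFit and eBayes, which share one estimate of the spread, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, two-sided. The contrasts were KO against WT at each stage and averaged over stages, the wild-type steps between stages, and a moderated F test for a genotype difference that changes with stage. These tests, the filter and most alternatives were chosen before the data were examined. The sets of developing probes, the position of arrays on the wild-type axis and the overlaps between stages were chosen afterwards. The sets were tested with camera at its preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the 6 tests. As the rule for named genes skips IDs, the probes named were, by its criterion, the 2 largest rises and 2 largest falls of each comparison among probes with adjusted p under 0.05 and non-overlapping arrays, or with the same sign at all stages for the average. They were ranked by fitted log2 difference, which gives no firm order where a group is near background.

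Where a probe was not well above background on any array of a group, its difference is given as a bound or not at all. Bounds come from normalized Cy3 means after scaling between arrays, with the dim group set to the higher of its own signal and the lowest signal among probes well above background, and bounds above the fitted fold are not given. Where that lowest signal of other probes is used a dye effect does not cancel, and such bounds are open to dye bias, since dyes were not swapped. Probe signal near background compresses differences, and the offset of 50 compresses them further.

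The procedure was tested on simulated data built from the wild-type means and the residual spread of the 27989 probes. Of simulated 2-fold changes it found 80.3% for KO against WT at E14.5, 84.8% at E16.5, 83.3% at E18.5 and 95.5% for the average. Of 1.5-fold changes it found 38.2%, 50.0%, 47.1% and 83.8%, and of 4-fold changes 100% in each, with 6 to 11 unchanged probes called. With no stage-dependent difference simulated the F test called 0 probes. The simulated noise was independent and normal, with the same spread for a probe in every group and no slide, array or between-probe structure. In the data the median SD of a probe was 0.07 in WT E14.5 and 0.20 in WT E18.5. The simulation therefore does not give the rate of wrong calls in the data.

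Whether replicate numbers pair arrays was checked by correlating the deviations of same-numbered arrays from their group means. At E16.5 the correlations between KO and WT were 0.29, 0.51 and 0.43 for numbers 1, 2 and 3, each above 0.1 and above those of other numbers. The numbers were therefore taken to pair the arrays there, which is an assumption. Deviations from a mean of 3 arrays depend on each other, so such a match can arise by chance, and the other comparisons did not show it. The labels do not state a pairing, and number 3 also marks the second scan batch. Alternatives covered the background correction, the normalization, the value table, the filter, replicate, scan batch and slide terms, the arrays in the fit, array weights, the variance model, a 1.5-fold minimum and leaving out each array. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.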

Results

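Fzd6 encodes a Frizzled receptor of the Wnt pathway, and the series followed the digit tips of mice without it through the stages at which the nail forms. RNA from the forelimb digit tips of wild-type and Fzd6-/- (KO) embryos was hybridised at 3 embryonic stages, E14.5, E16.5 and E18.5 (days after mating). Each of the 6 groups of genotype and stage held 3 arrays, 18 in all, and the design text describes RNA taken from each embryo of 3 wild-type (WT) and 3 KO mice per stage. On every array the digit-tip RNA carried the green dye Cy3, and a common reference RNA carried the red dye Cy5. Values are log2 of the Cy3 signal over the Cy5 signal, so a higher value means more of that RNA in the digit tip. Between 59.8% and 69.2% of the 42006 probes were well above background in Cy3 on each array, and 27989 probes were tested. The number of arrays, 3 per group, limits the precision of every difference.

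All 42006 probes carry an ID, and the files do not pair these IDs with genes. The probe for Fzd6 was therefore not analysed here, and the genotype labels were not checked against the level of the targeted gene. Each probe is a DNA sequence of 60 bases, and the probes described here are named by ID and, for those that differed by genotype, by sequence.

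Stage separated the arrays most. The first principal component of the tested probes held 56.7% of the variance, and the next held 11.8%. Arrays of one group correlated across probes at r = 0.989 to 0.992 for WT E14.5, 0.960 to 0.975 for KO E14.5 and 0.949 to 0.964 for WT E16.5. For KO E16.5 the range was 0.964 to 0.985, for WT E18.5 it was 0.919 to 0.953, and for KO E18.5 it was 0.961 to 0.985. WT E18.5 replicate 1 stood farthest from its group, with 254 probes at least 2-fold above both other arrays and 682 at least 2-fold below both. WT E16.5 replicate 2 followed, with 114 above and 139 below.

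The wild-type arrays describe how the digit tip changed between the sampled stages. From E14.5 to E16.5, 7932 probes changed, of which 3562 rose and 4370 fell. Among changes of at least 2-fold, rises outnumbered falls, with 1240 against 384. The probe Z00033785-1 was well above background on 1 of 3 WT arrays at E14.5 and measured 7.17 ± 0.14 (SD, n = 3) at E16.5, with adjusted p = 1.27e-07 by limma. In the same interval Z00026015-1 went from not well above background on all 3 WT E14.5 arrays to 6.89 ± 0.10 (SD, n = 3), with adjusted p = 3.65e-07. Z00035258-1 changed by -2.83 ± 0.57 (SE) and Z00056592-1 by -2.77 ± 0.35. The size for Z00035258-1 depended on the processing, at -1.63 with Agilent's processed signals (limma adjusted p = 0.0381) and -3.49 with Cy3 alone.

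These calls rest on moderated tests in limma at a Benjamini-Hochberg adjusted p under 0.05. The 3 arrays of each stage did not overlap at 49.0% of tested probes, where chance gives 10%. With median centring in place of loess 2135 probes passed and 56.9% of them were higher, against 44.9% in the reported fit, so the majority direction depended on the normalization. It also turned without WT E16.5 replicate 2, with 3104 higher and 2841 lower. Within the first scan batch alone, with 2 arrays per group, 5357 probes passed, and 95.6% of these had the same direction in the second batch. The share over all tested probes was not computed, here or for the comparisons below.

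From E16.5 to E18.5, 4857 probes changed in the wild type, of which 2077 rose and 2780 fell. Z00073883-1 rose by 5.76 ± 0.48 log2 (SE, n = 3 per group) and Z00071978-1 rose by 5.71 ± 0.35. The WT E18.5 arrays spread widely for Z00073883-1, at 1.82 ± 1.54 (SD, n = 3). Z00071877-1 went from 6.71 ± 0.15 (SD) to 0.72 ± 0.77, with adjusted p = 2.29e-07, and at E18.5 it was well above background on 2 of 3 arrays. The call was lost with Agilent's processed signals (adjusted p = 0.0618) and with the value table (adjusted p = 0.0603). Z00034626-1 changed by -4.75 ± 0.25. The arrays did not overlap at 24.5% of tested probes, where chance gives 10%.

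This count was the least stable of the stage comparisons. It was 1708 without WT E16.5 replicate 1, 2890 without WT E18.5 replicate 3, 1457 with slide as a fixed term and 217 when only the 6 arrays compared were fitted. It was 2201 within the first scan batch, of which 90.0% had the same direction in the second, and 665 with median centring, of which 12.6% were higher against 42.8% as reported. Without WT E18.5 replicate 1 the majority turned, with 3621 higher and 2909 lower, as it did without background subtraction, with 4426 and 4201.

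**Figure D1:**
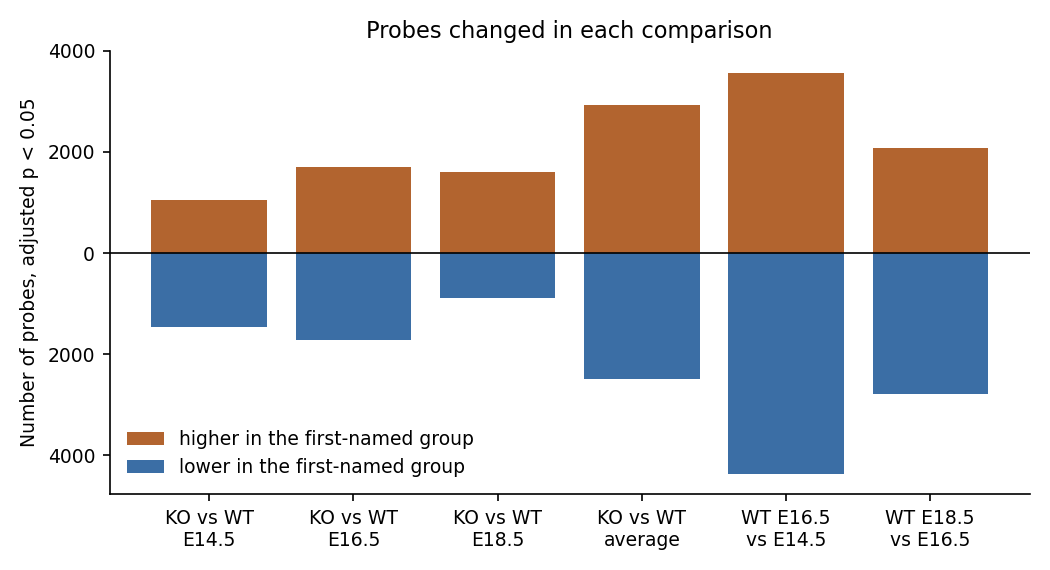
Bars give the number of probes with adjusted p under 0.05 (vertical axis, count of probes) in each comparison, upward for probes higher and downward for probes lower in the group named first. The WT change from E14.5 to E16.5 held the most probes, 7932, and the E18.5 genotype comparison had 1595 higher and 882 lower. All comparisons share a single estimate of spread, though the spread differed between groups, so the bars are not directly comparable.

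At E14.5, the earliest stage sampled, 2505 probes differed between KO and WT digit tips. Of these, 1044 were higher in KO and 1461 lower, and among the 500 with at least a 2-fold difference 369 were lower. Z00028661-1 (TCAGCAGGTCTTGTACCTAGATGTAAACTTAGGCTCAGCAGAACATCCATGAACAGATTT) measured 2.15 ± 0.14 (SD, n = 3) in KO and was not well above background on any of the 3 WT arrays, so that KO was at least 20.8-fold higher, with adjusted p = 1.39e-07. Z00073883-1 (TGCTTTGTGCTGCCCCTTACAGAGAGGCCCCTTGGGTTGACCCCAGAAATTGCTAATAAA) was 4.18 ± 0.48 log2 (SE) higher in KO. Z00070639-1 (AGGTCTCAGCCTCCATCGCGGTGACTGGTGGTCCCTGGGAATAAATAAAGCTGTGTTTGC) measured -0.23 ± 0.10 (SD) in KO against 3.51 ± 0.04 in WT, a difference of -3.74 ± 0.24 (SE). Z00074193-1 (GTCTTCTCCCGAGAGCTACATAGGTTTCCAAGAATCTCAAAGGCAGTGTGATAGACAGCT) was lower in KO, where it was well above background on 2 of 3 arrays, and measured 0.43 ± 0.06 (SD) in WT, with adjusted p = 2.75e-09.

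The limma test was that of the stage comparisons. The 3 arrays of each genotype did not overlap at 39.5% of tested probes, where chance gives 10%. KO and WT E14.5 arrays lay largely on different slides. With slide as a fixed term 624 probes passed, and with scan batch as a fixed term 2547 did. Within the first scan batch 1116 passed, of which 98.9% had the same direction in the second batch, where one KO and one WT array shared a slide. The count fell to 1495 without WT replicate 1, 1458 without WT replicate 2 and 1656 without KO replicate 2. It was 3946 without background subtraction, 431 with median centring and 5383 when only the 6 arrays compared were fitted. With Cy3 alone the excess of lower probes was lost, with 1876 higher and 1838 lower.

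At E16.5 the genotypes differed at 3424 probes, 1702 higher and 1722 lower in KO, and among the 613 with at least a 2-fold difference 432 were lower. Z00040994-1 (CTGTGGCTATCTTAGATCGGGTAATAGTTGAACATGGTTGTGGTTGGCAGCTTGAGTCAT) measured 0.72 ± 1.19 (SD, n = 3) in KO against 6.27 ± 0.27 in WT, a difference of -5.55 ± 0.44 log2 (SE) with adjusted p = 9.15e-07. Z00046024-1 (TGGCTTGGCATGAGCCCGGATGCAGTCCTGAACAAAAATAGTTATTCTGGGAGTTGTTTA) measured 4.11 ± 0.36 (SD) in WT and was not well above background on all 3 KO arrays, at least 29.8-fold lower, with adjusted p = 1.12e-11. Z00073883-1 was 3.65 ± 0.48 (SE) higher in KO. Z00027416-1 (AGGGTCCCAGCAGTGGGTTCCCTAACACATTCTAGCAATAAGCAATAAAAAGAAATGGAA) was not well above background on the 3 WT arrays and at least 9.95-fold higher in KO.

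The arrays of the genotypes did not overlap at 30.7% of tested probes, where chance gives 10%. No slide held KO and WT arrays of this stage, and a fixed slide term could not be fitted. The reported fit did not use the pairing of replicate numbers taken for this stage. With slide as a random block 3618 probes passed, and with scan batch as a fixed term 3578 did. Within the first scan batch 1835 passed, of which 98.4% had the same direction in the second. The genotypes lay on different slides in both batches, so this does not part genotype from slide. The count was 2151 without WT replicate 1, 2173 without KO replicate 1 and 2170 without KO replicate 3, 5243 without background subtraction, 516 with median centring and 2014 when only the 6 arrays compared were fitted. The near-even directions were not stable. There were 774 higher and 1240 lower when only these arrays were fitted, 1044 and 1478 without WT replicate 2, and 2088 and 1700 without WT replicate 3.

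The probes that differed at E16.5 were then set against the wild-type course, using the change from WT E14.5 to WT E18.5. This change shares no array with the E16.5 comparison. It does share each probe's estimate of spread, so the numbers for independent lists can be too low a reference. These sets were chosen after the data had been seen. Of 5286 probes that rose in the wild type from E14.5 to E18.5, 1075 were lower in KO at E16.5 and 101 were higher, where independent lists would share 325 and 321. The set lay below other probes in KO (median -0.20 log2, camera adjusted p = 5.11e-21, and adjusted p = 0.0255 with an estimated correlation). Of 7056 probes that fell in the wild type, 922 were higher in KO and 136 lower, with a median of 0.16 log2. For this set camera gave adjusted p = 1.24e-14, and the call was lost at adjusted p = 0.177 with an estimated correlation. The rotation test fry, which asks whether a set moves on balance one way, gave adjusted p = 0.00154 and 0.0349 for the sets. At E14.5 the sets came from the WT change from E16.5 to E18.5. Of 2077 probes that rose there, 209 were lower in KO and 140 higher, against 108 and 77.5 for independent lists (camera adjusted p = 0.766). Of 2780 that fell, 216 were lower and 58 higher, against 145 and 104, with camera adjusted p = 0.0445, lost at adjusted p = 0.974 with an estimated correlation.

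Each array was also placed on the axis from the WT E14.5 mean (0) to the WT E18.5 mean (1), with that array left out of the means. KO E16.5 arrays lay at 0.41 ± 0.05 (SD, n = 3) and WT E16.5 arrays at 0.69 ± 0.08, without overlap. The difference of -0.28 had an exact two-sided permutation p of 0.1, the smallest that 3 arrays against 3 can give. Within the assumed pairs of replicates 1, 2 and 3 the difference was -0.28, -0.32 and -0.23. An exact two-sided permutation of signs over these 3 pairs gave p = 0.25, the smallest it can give. The difference was -0.30 in the first scan batch and -0.23 in the second. At E14.5 the difference was -0.08 (permutation p = 0.2) and at E18.5 it was 0.03 (permutation p = 0.8), both two-sided. At these stages the WT arrays define the axis and the KO arrays do not, so these p-values are not exact. The E16.5 difference was compared with that at E18.5 in a permutation test of 400 permutations with the same limit, p = 0.04 and 0.12 after adjustment over 3 such comparisons. It did not use the pairs, and the stages were not shown to differ on this measure.

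**Figure D2:**
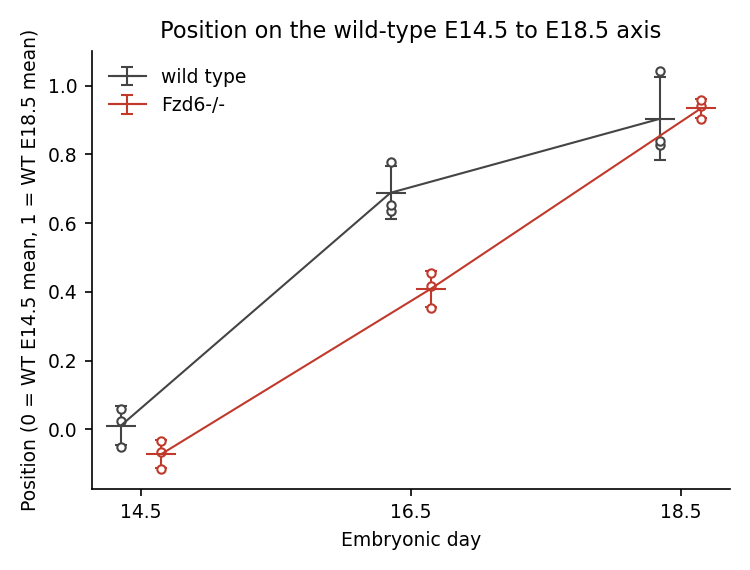
The vertical axis is the position of each array between the WT E14.5 mean (0) and the WT E18.5 mean (1), without unit, against embryonic day. Open circles are single arrays, and horizontal bars with error bars are group means ± SD (n = 3). At E16.5 the KO arrays lie between 0.354 and 0.457 and the WT arrays between 0.636 and 0.777.

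At E18.5, 2477 probes differed, 1595 higher in KO and 882 lower. Z00040594-1 (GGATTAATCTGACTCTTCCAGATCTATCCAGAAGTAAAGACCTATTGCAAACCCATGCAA) measured 4.34 ± 0.04 (SD, n = 3) in KO against 0.18 ± 0.11 in WT, where it was well above background on 2 of 3 arrays. The adjusted p was 8.6e-14. Z00023034-1 (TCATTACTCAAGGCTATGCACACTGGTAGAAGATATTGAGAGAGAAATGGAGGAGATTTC) measured 3.32 ± 0.50 (SD) in KO and was well above background on 1 of 3 WT arrays, with adjusted p = 2.59e-06. Z00057348-1 (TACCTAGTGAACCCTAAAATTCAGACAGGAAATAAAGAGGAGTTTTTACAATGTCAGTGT) measured 3.59 ± 1.07 (SD) in WT and was not well above background on all 3 KO arrays, with adjusted p = 2.07e-05. Z00012139-1 (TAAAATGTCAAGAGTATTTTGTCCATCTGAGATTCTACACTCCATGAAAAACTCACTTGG) differed by -3.23 ± 0.28 log2 (SE).

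The arrays did not overlap at 23.4% of tested probes, where chance gives 10%. The excess of higher probes, 64.4% as reported, depended on the processing and on one array. The share was 53.1% without background subtraction, 49.3% with Agilent's processed signals, 49.1% with Cy3 alone, 48.8% with the deposited value table and 77.1% with median centring. Without WT replicate 1, which stood apart from its group, 1049 probes were higher and 1086 lower. The count was 5848 without WT replicate 2, 1252 without WT replicate 3, 1643 without KO replicate 1 and 1298 without KO replicate 2. It was lowest when only the 6 arrays compared were fitted, at 326 (169 higher and 157 lower), and was 358 with median centring. The reported fit shared a single estimate of spread, though the median SD of a probe ranged from 0.07 (WT E14.5) to 0.20 (WT E18.5). The counts of different stages are therefore not directly comparable. No slide held KO and WT arrays of E18.5 either, and a fixed slide term could not be fitted. The count was 2624 with slide as a random block and 2485 with scan batch as a fixed term. Within the first scan batch 461 passed, of which 94.6% had the same direction in the second, with the genotypes again on different slides in both batches.

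Averaged over the 3 stages, with 9 arrays per genotype, 5416 probes differed, 2923 higher in KO and 2493 lower. Differences of at least 2-fold were fewer, with 97 higher and 160 lower. Z00070639-1 was lower in KO at every stage, at -3.43 ± 0.14 log2 (SE, n = 9 per genotype) on average, with adjusted p = 1.5e-10. Z00073883-1 was higher in KO by 3.03 ± 0.28. Z00057348-1 was lower in KO, where it was well above background on 1 of 9 arrays, and averaged 3.42 in WT. Z00027416-1 was higher in KO, at 0.36 on average, and was well above background on 2 of 9 WT arrays, so the size of either difference is set by the background. Within the first scan batch 2655 probes passed, with 1214 under median centring. The excess of higher probes turned under several alternatives. There were 3306 higher and 3816 lower without background subtraction, 3368 and 3493 with processed signals, and 2310 and 2326 with the value table. Without WT E18.5 replicate 1 there were 2737 and 3064, without the 4 arrays that stood apart 2296 and 2822, and within the first scan batch 1298 and 1357.

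Probes that differed by genotype at one stage often did so in the same direction at another, and these comparisons share no arrays. They do share each probe's estimate of spread, so the numbers for independent lists can be too low a reference. KO arrays of E16.5 and E18.5 also lay on the same slides, as did WT arrays of E14.5 and E16.5. For E14.5 and E16.5, 557 probes were lower in KO and 577 higher at both, where independent lists would share 89.9 and 63.5. For E16.5 and E18.5 the numbers were 338 lower and 274 higher, against 54.3 and 97.0, and for E14.5 and E18.5 they were 320 and 198, against 46.0 and 59.5. Opposite calls also occurred. For E16.5 and E18.5, 154 probes were lower and then higher in KO, more than the 98.1 of independent lists, and 17 were higher and then lower, against 53.6. For E14.5 and E16.5 the opposite calls were 31 and 5, against 88.8 and 64.2, and for E14.5 and E18.5 they were 61 and 22, against 83.3 and 32.9. At all 3 stages 237 probes were lower and 170 higher, against 2.83 and 3.62 for independent lists. Among these, 59 were at least 2-fold lower and 26 at least 2-fold higher at each stage. Across all tested probes, which are not independent replicates, the genotype differences correlated at r = 0.49 between E14.5 and E16.5, 0.27 between E16.5 and E18.5 and 0.14 between E14.5 and E18.5.

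The genotype difference itself changed with stage at 2450 probes, by limma's moderated F test. Of these, 255 had called differences of opposite sign at a pair of stages. By call, 458 of the 2450 differed between genotypes at E14.5 alone, 538 at E16.5 alone and 619 at E18.5 alone. No slide held both genotypes at E16.5 or E18.5, so a difference between slides cannot be told apart from such a change. Z00046024-1 measured 4.11 ± 0.36 (SD, n = 3) in WT at E16.5, against 0.12 ± 0.11 at E14.5 and 0.35 ± 0.24 at E18.5, and was not well above background on any KO array. It was called lower in KO at all stages, with limma adjusted p = 0.000347 at E14.5 and 0.000617 at E18.5. Z00040594-1 measured 3.15 ± 0.11 in KO at E16.5 and 4.34 ± 0.04 at E18.5, and was well above background on 1 of 3 KO arrays at E14.5. In WT it was not well above background on any array at E14.5 and E16.5. For both probes the dimmer genotype lay near background, so the size of the difference follows the level of the other genotype. The F test cannot tell a lasting difference from a changing one there. The count was 557 within the first scan batch, 4473 without background subtraction, 4316 with Cy3 alone and 216 with median centring. It was 3975 without WT E18.5 replicate 2, 1432 without KO E18.5 replicate 2, and 1546, 1571 and 1603 without WT E14.5 replicates 1, 2 and 3.

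**Figure D3:**
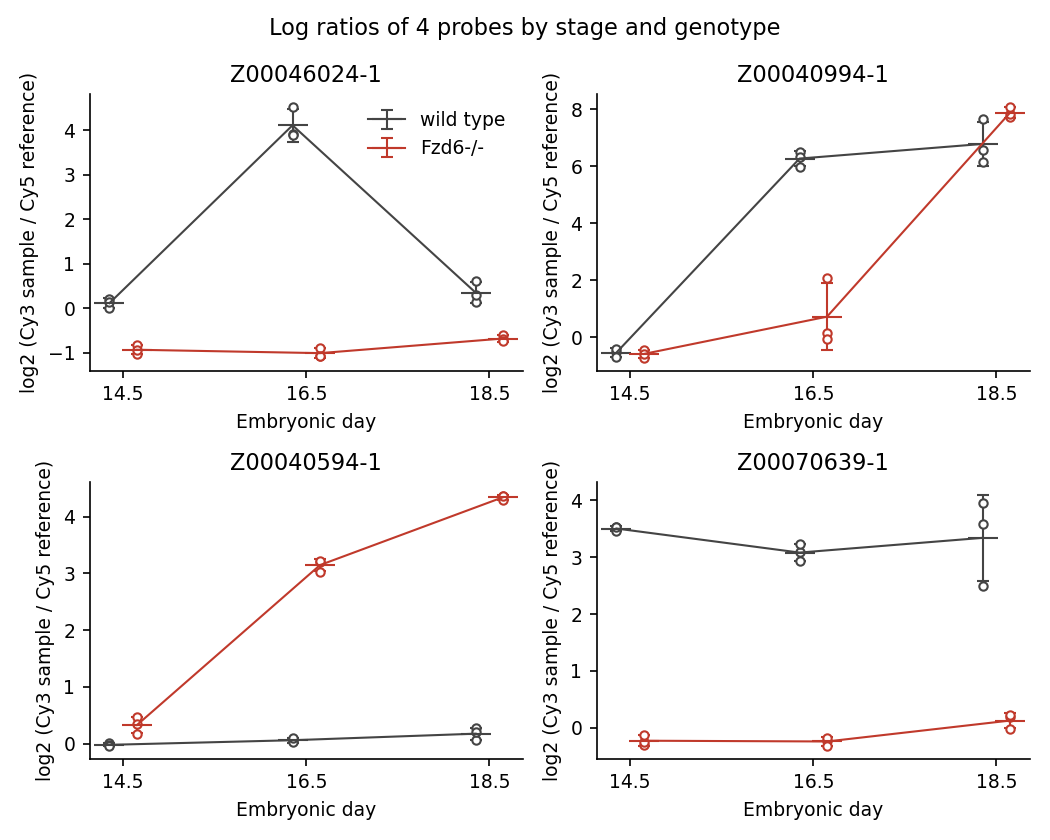
Each panel plots one probe, with log2 of Cy3 sample over Cy5 reference on the vertical axis and embryonic day on the horizontal axis. Open circles are single arrays, and horizontal bars with error bars are group means ± SD (n = 3). Z00070639-1 is lower in KO at each stage, while Z00040594-1 reaches 4.34 in KO at E18.5. In WT the latter was well above background on 2 of 3 arrays at E18.5 and on none earlier.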

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

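Every test of an explanation in this part, the tests over other splits of the arrays included, was chosen after the results it examines had been seen.

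The difference between genotypes changed with stage at 2450 probes by the moderated F test. Each probe's average genotype difference was first taken out of the KO arrays, so that only the dependence on stage was left to test. Of 100 splits drawn within stages, 1 gave as many probes, the real one, and the highest other gave 451. Chance was excluded at the 0.05 level over such splits, which did not use the pairing taken for E16.5. The other splits mix the genotypes, which adds to the spread and lowers their counts. The splits did not follow slides either. Since no slide held both genotypes at E16.5 or E18.5, a difference between slides cannot be told apart from this result. Of the 18 named probes, 10 passed the test of the difference between stages. The named probes were picked from the same arrays for their large differences, which favours passing, so this share adds no support. Z00046024-1 (adjusted p = 2.36e-08) was high in WT at E16.5 alone, at 4.11 against 0.12 at E14.5 and 0.35 at E18.5, and in KO it was not well above background on any array. It was called lower in KO at E14.5 and E18.5 as well (limma adjusted p = 0.000347 and 0.000617). Z00040594-1 (adjusted p = 1.97e-10) measured 3.15 and 4.34 in KO at E16.5 and E18.5, and in WT it was well above background on 2 arrays, both of E18.5. For both probes the dimmer genotype lay near background, so the size of the difference follows the level of the other genotype. Whether the difference itself changed cannot be told there. Z00040994-1 (adjusted p = 3.63e-05) reached 6.27 in WT at E16.5 and 0.72 in KO, and at E18.5 the levels were 6.79 and 7.88. Z00023034-1 (adjusted p = 0.000116) measured 3.32 in KO at E18.5, and in every other group it was well above background on at most 1 of 3 arrays. Z00028661-1 (adjusted p = 0.000149) was at least 20.8-fold higher in KO at E14.5, where no WT array measured it well above background, and 1.76 log2 higher at E16.5, while at E18.5 no difference was called (adjusted p = 0.169). Z00073883-1 (adjusted p = 0.0246) was higher in KO by 4.18 at E14.5 and 3.65 at E16.5, and at E18.5 no difference was called (adjusted p = 0.113). There it was 1.25 higher in KO, with KO arrays at 3.07 ± 0.18 (SD) and widely spread WT arrays at 1.82 ± 1.54. The other 4 were named for the wild-type steps, Z00033785-1 (adjusted p = 0.0300), Z00026015-1 (adjusted p = 0.00479), Z00071877-1 (adjusted p = 0.00150) and Z00034626-1 (adjusted p = 0.0214).

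KO arrays at E16.5 lay nearer to WT E14.5 than WT E16.5 arrays did, with a difference of -0.279 on the wild-type axis, and 1997 of the E16.5 calls pointed towards E14.5 against 237 towards E18.5. A difference between scan dates was argued against, since both dates held arrays of both genotypes and the difference within a date was -0.301 for the first and -0.235 for the second. A difference between slides cannot be told apart from this, since no slide held both genotypes at E16.5. The largest shift within a group between its own slides was 0.21 (WT E18.5), below that difference by less than the SD of such shifts over the 6 groups, 0.107. Younger embryos in the KO group cannot be told apart from an effect of genotype either. Of the calls towards E14.5, 1875 did not differ one way at all 3 stages, and 1.44% of these were shown to lie beyond WT E14.5, which an age difference allows, and no independent measure of age was used here. Of all 3424 E16.5 calls, 703 (20.5%) lay beyond both WT E14.5 and WT E16.5, which an age difference alone does not give unless a probe turns between sampled stages. Of these, 323 differed one way at all 3 stages and 380 did not, and for the shift itself younger age stays open. Under the alternatives tried the position difference was -0.235 to -0.319. A slower course of the digit tip without Fzd6 was not tested apart from these.

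For the comparisons of 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In each of them 1 split, the real one, gave as many probes. The other splits mix arrays of the groups compared, so a real difference adds to the spread and lowers their counts. Those counts therefore do not give the number of calls under chance. At E14.5 the real split gave 2505 probes and the highest other 0, at E16.5 3424 and 8, and at E18.5 2477 and 305. At E16.5, where the replicate numbers were taken to pair the arrays, 4 splits part all 3 pairs, and the highest other of these gave 0 probes. For WT E16.5 against E14.5 the numbers were 7932 and 1, and for WT E18.5 against E16.5 they were 4857 and 3986. That last split set WT E18.5 replicates 1 and 3 with WT E16.5 replicate 2 and followed no slide or scan batch. It joined arrays that stood apart from their groups, with 936 probes 2-fold from both others for WT E18.5 replicate 1 and 253 for WT E16.5 replicate 2. A count near the real one thus came from a split that did not fully part the stages. For the average over stages 1 of 100 splits, the real one, gave 5416 probes, and the highest other gave 3307. Chance was excluded at the 0.05 level over such splits, which did not use the E16.5 pairs or follow slides. The counts of the other splits have the same limit, and a difference between slides at E16.5 and E18.5 stays open.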

How the results depend on the processing

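Leaving out 4 arrays that stood apart and fitting the first scan batch alone were chosen after the data had been seen, as were all alternatives for the 407 probes changed one way at all 3 stages and for the position difference. Values are in the order KO against WT at E14.5, E16.5, E18.5 and averaged, WT E16.5 against E14.5, WT E18.5 against E16.5, and the change of the genotype difference with stage, where given. Reported counts were 2505, 3424, 2477, 5416, 7932, 4857 and 2450.

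Median centring gave 431, 516, 358, 1214, 2135, 665 and 216, and 78 probes at all stages. Without background subtraction 3946, 5243 and 3779 probes passed by stage, 8627 for WT E18.5 against E16.5, 4473 for the change with stage and 631 at all stages. WT E18.5 against E16.5 gave 8535 with Agilent's processed signals and 7756 with Cy3 alone, which gave 4316 for the change with stage. A fixed slide term gave 624 at E14.5 and 1457 for WT E18.5 against E16.5. Fitting only the arrays compared gave 5383, 2014 and 326 by stage and 217 for WT E18.5 against E16.5. Array weights gave 6562 at E14.5, 3988 at E18.5 and 5067 for the change with stage. A 1.5-fold minimum, which can only lower counts, gave 1340, 1734, 1384, 961, 3965 and 2270. The first scan batch, with fewer arrays, gave 1116, 1835, 461 and 2655, 2201 for WT E18.5 against E16.5, 557 and, at all stages, 148. Apart from the last 2 settings the cause was not tested.

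With each array left out in turn the counts ranged from 1458 to 2053, 2151 to 3788, 1252 to 5848, 4048 to 6858, 5553 to 8061, 1708 to 6530 and 1432 to 3975. The other alternatives kept each count within 1.5 times. The 4 arrays that stood apart were the most deviant array of each group that held an array with over 100 probes 2-fold from both others, WT E16.5 replicate 2, WT E18.5 replicate 1, KO E14.5 replicate 2 and KO E18.5 replicate 1. WT E18.5 replicates 2 and 3 were kept, though with 170 and 207 such probes they exceeded the KO arrays left out, at 147 and 133. Without the 4 the counts were 2591, 3651, 2104, 5118, 7254, 6730 and 2252. The replicate block gave 2390, 3278, 2203, 5172, 7761, 4604 and 2174 and moved no count by over 1.5 times. Outside the E16.5 genotype comparison the numbers were not taken to pair arrays. In each other comparison some same-number correlation was at most 0.1, and not every array correlated best with its own number. Of 393 values of named probes under alternatives, 391 kept direction and call and 0 reversed. This overstates stability, since these probes were picked as the largest differences in the same data. Scaling between arrays leaves log ratios as they were, so its values and counts could not change. Replicate and scan-batch terms are balanced over the groups. They could change the spread and the calls, but not the differences of probes with all values. The value table largely repeats the processed signals. Z00071877-1 lost its call in WT E18.5 against E16.5, at -2.89 (adjusted p = 0.0618) with processed signals and -2.89 (adjusted p = 0.0603) with the value table. Alternatives over the probes of a gene, Fzd6 and gene lists were not run. Signal over background limits dim probes to bounds.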

Other observations

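The tests of explanations in this part were chosen after the results had been seen.

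From E14.5 to E16.5, 6632 probes changed in KO, 3413 rising and 3219 falling, and from E16.5 to E18.5, 7519 changed, 3867 rising and 3652 falling. The wild type had 7932 changes in the first interval and 4857 in the second, and whether these counts differ between genotypes was not tested. Over the whole span from E14.5 to E18.5 the wild type changed at 12342 probes. Of 3562 probes that rose in the wild type by E16.5, 397 were higher and 146 lower in KO at E18.5, where independent lists would share 203 and 112. The comparison shares no array but does share each probe's estimate of spread. No shift of the set was shown, with camera adjusted p = 0.0550, adjusted p = 0.974 with an estimated correlation and adjusted p = 0.203 by fry.

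A set of 85 probes differed by at least 2-fold at every stage, 59 lower and 26 higher in KO. A difference between slides or scan dates was argued against, since 69 such probes picked on the first 3 slides had a median difference of 1.69 log2 in the called direction between KO and WT E14.5 arrays sharing the fourth slide, and 61 of them were at least 2-fold apart there. A sequence variant under the probe would lower binding by the same factor at all stages. Of the 62 probes whose lower group was well above background on all its arrays, 6 had a difference that changed with stage. Signal near background and the offset of 50 compress differences, so a constant factor can vary in size where the level changes with stage. The change with stage therefore cannot decide whether these 6 probes carry a variant. For the other 79 probes a variant and a lasting change of expression cannot be told apart either. The probes have no gene or position here. Genes lying near the deleted one and carried along with it may be among them, which was not tested.

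A pair of probes, chosen after their values were seen, moved in opposite ways within groups. Z00064853-1 ranged from -5.40 to 0.91 and Z00016441-1 from -2.86 to 2.94 over the 18 arrays. On the 6 arrays of the second scan batch the first lay between -5.40 and -3.14 and the second between 2.58 and 2.90. On the 12 arrays of the first batch they spanned -5.09 to 0.91 and -2.86 to 2.94. Whether the scan batch or another property of these arrays goes with the narrower range was not tested. Across deviations from group means 5 other probes followed the first at r above 0.9, and 2 opposed it at r below -0.9, among probes with an SD above 0.5. The labels give the embryos as of mixed sex, and sex was not tested.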
